A study of Mus musculus with 2 samples.

How the data were processed

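RNA from MC3T3-E1 mouse osteoblastic cells was sequenced in 2 libraries, 1 from untreated cells and 1 from cells given 10 nM PTH, both labelled 1 h. Per the labels, cells were kept in medium with 10% serum, seeded at 25000 cells per cm2 in 12-well plates and treated 24 h later. The labels name total RNA as the extracted molecule and give no selection or depletion step, and no strand or read layout. The labels put each library in its group, and nothing in them states how the libraries were batched.

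The authors deposited 1 table of read counts per gene with 1 column per library, as whole numbers that were not normalised. Per the submitters' processing notes, reads were aligned with HISAT2 and the mm10 build was used, and the version of HISAT2 is not given in the sources used here. The counting tool, the gene annotation and any use of strand in counting are not given in the sources used here either. The table holds 55487 rows named by Ensembl gene and symbol, of which 23527 had a count in either library. The column totals were 66302211 for the untreated and 70036872 for the PTH library. The 10 rows with the most counts took 11.0% and 10.2% of the totals. Of the gene identifiers, 55227 have an entry in GENCODE release M21 (GRCm38, the assembly also called mm10), from which gene type, coordinates, exonic length, GC content and shared exons were taken. How reads were assigned is unknown for rows that share exons, antisense overlaps and genes with pseudogenes or near-identical copies. The larger overlaps and some such copies are marked as uncertain in the text. Smaller overlaps are not marked, such as 8.01% of Crem and 7.28% of Jun on the opposite strand and 6.57% of Usp50 on the same strand. A gene without a mark may therefore still overlap another. Of the gene symbols, 114 stand on more than 1 row, and the rows were kept apart.

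Counts were scaled by edgeR's TMM effective library sizes (edgeR 4.0.16 in R 4.3.3), computed on the 16408 rows with a total count of 20 or more over both libraries. edgeR's quasi-likelihood test could not be fitted, because 1 library per group leaves no residual degrees of freedom, and no p-value was computed. The measure is the ratio of scaled counts, PTH over untreated, with a 95% exact conditional (Clopper-Pearson) interval computed in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3; plots were drawn with matplotlib 3.10.9. Intervals and floors cover counting error only, with each read taken as independent. Reads copied by PCR are not independent molecules, so the counting error itself may be wider than these intervals. A row is past the rule of size when its whole interval lies beyond 1.5-fold. For log2 ratios 0.5 count was added to each library. Under sampling alone a count of 0 allows up to 3 counts, which is 0.0447 CPM (counts scaled by library size) in the untreated and 0.0434 in the PTH library. The table holds more zeros than sampling gives, so a listed 0 is not read as that bound.

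The 23 gene lists, the rule of size, the filter, the alternatives and the rule for named genes were set before the data were examined. The rule names the 15 highest and 10 lowest rows by the interval bound nearest 1, leaving out predicted gene models, up to 4 members per list with the bound farthest from 1, the members with most counts where fewer than 2 are past the rule, and 10 genes named in advance, Pth1r, Gprc5a, Tnfsf11, Runx2, Nr4a1, Nr4a2, Fos, Crem, Rgs2 and Pde4d. It names 81 genes, and other list members in the text were picked as examples after their values were seen. Lists can share members, such as Dusp1, Sik1, Pde4b and Rgs2. For lists with at least 5 measured members the median log2 ratio is given with its percentile among 10000 random lists of the same size, matched over 20 bins of mean expression, as a description of these libraries.

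The interval and the rule were tested on simulated data for PTH against untreated, with counts drawn for the 16408 rows from the real means and library sizes and 200 of them changed. The rule called 82% of rows changed 2-fold, 96% of those changed 4-fold, 76% of those changed to 0.5 and 86% of those changed to 0.25, and 3 of 16208 unchanged rows. With a simulated coefficient of variation of 0.2 between cultures and no change, it called 1216 of 16408 rows, and 22 with an interval widened by the same variation. With 0.1 it called 19, and 5 when widened. None of these simulations held the excess of zeros seen in the table, so their error counts do not cover rows listed at 0. Of the real rows past the rule, 83 were at 0 untreated and 63 at 0 after PTH. The widened interval was a normal approximation on the log scale with 0.5 count added to each library, not the exact interval. The variation between cultures is unknown with 1 library each. Alternatives were 3 other scalings (total counts, the median-of-ratios size factors of DESeq2 1.42.0, and edgeR's upper-quartile factors), other count filters and fold limits, widened intervals, thinning of the deeper library, summed symbols, a pseudocount of 5 and unmatched random lists. Others were added after the data were seen. No rows were left out of the comparison apart from those under the count minimum, and 1 gene that the rule names is not reported here.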

Results

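MC3T3-E1 cells, an osteoblast-like line derived from mouse calvaria, were sequenced as RNA after 1 h with 10 nM parathyroid hormone (PTH) and after 1 h without it. PTH is a peptide hormone that acts on osteoblasts through Pth1r, a receptor coupled to cyclic AMP production. Each condition had 1 library. The untreated library held 66302211 counts over genes and the PTH library 70036872, and 16408 of 55487 rows had a total count of 20 or more and entered the comparison. With 1 library per condition, no difference below has a replicate check and no p-value was computed. Each interval in brackets is a 95% exact interval of the ratio. It covers counting error only, with reads taken as independent, and compares these libraries, not the conditions.

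The comparison asks which genes had more or fewer reads after 1 h of PTH. With a counting interval wholly above 1.5-fold, 15 of 17 measured cyclic AMP target genes and 13 of 22 genes of the cytokine, chemokine and growth factor list had more reads in the PTH library. Of these 13, 2 (Cxcl1 and Cxcl5) were listed at 0 counts untreated and are less certain. Rgs2, which limits signalling by G proteins, was 50-fold higher (41.8 to 60.3), Nr4a2, an orphan nuclear receptor, 13.6-fold higher (12.9 to 14.3), and Crem, a cyclic AMP-responsive transcription factor, 12.2-fold higher (10.6 to 14.2). The cytokine gene Il6 was 31.6-fold higher (22.9 to 44.9), and Tnfsf11, which encodes the osteoclast differentiation factor RANKL, was 28.2-fold higher (15.9 to 55.0). In the other direction, Jun, a subunit of the AP-1 transcription factor, was 6.73-fold lower in the PTH library (6.42 to 7.06), and Ccn2, a matrix-associated growth factor gene that responds to SRF and YAP, was 3.66-fold lower (3.62 to 3.69). None of 18 cell cycle genes had an interval wholly beyond 1.5-fold, and Col1a1, a collagen gene, was at a ratio of 1.05 (1.05 to 1.05).

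A row was taken as past the rule of size when its whole counting interval lay beyond 1.5-fold. By this rule 884 rows had more reads after PTH, 573 of them protein-coding genes, and 581 had fewer, 391 of them protein-coding. The interval lay beyond 4-fold for 179 of the rows with more reads and for 93 of those with fewer. The median log2 ratio over the compared rows was 0.00. Among the 9549 rows with at least 1000 counts, 95% lay between log2 ratios of -0.56 and 0.85, and the SD was 0.39. When the interval was widened for an assumed variation between cultures (a coefficient of variation of 0.2 per library), 474 rows kept more reads by the rule and 267 kept fewer.

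**Figure D1:**
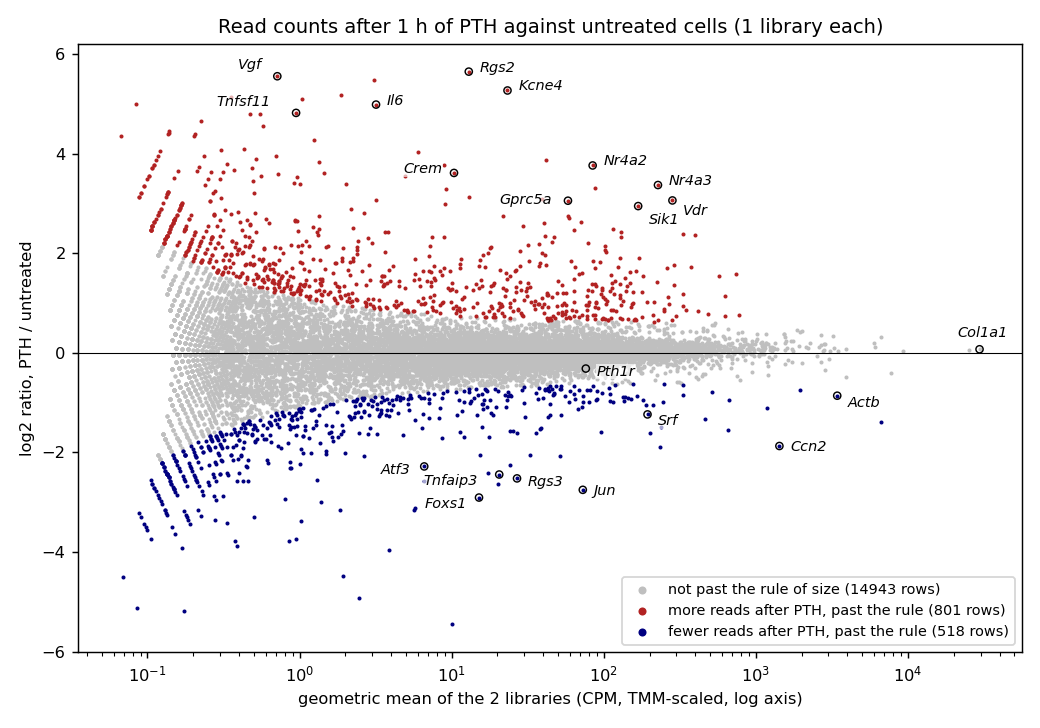
Log2 ratio of PTH to untreated counts (vertical axis) against the geometric mean of both libraries in CPM (counts scaled by library size), TMM-scaled, on a log axis,, for rows with counts in both libraries; each point is 1 row, with 1 library per condition. Red marks 801 rows with more reads after PTH and blue 518 with fewer past the rule of size, grey the other 14943; of the genes with a name in the plot, Rgs2 is highest and Foxs1 lowest.

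The 15 rows ranked highest by the bound of the interval nearest a ratio of 1 included Rgs2, Il6 and Tnfsf11. Kcne4, an accessory subunit of voltage-gated potassium channels, was 38.5-fold higher (33.9 to 43.8), with 252 counts untreated and 9982 after PTH. Cbarp, which binds a subunit of voltage-gated calcium channels, was 14.5-fold higher (13.5 to 15.7), and Has1, a hyaluronan synthase, 16.3-fold higher (13.3 to 20.1). Vgf, the precursor of secreted neuropeptides, went from 7 to 338 counts, a ratio of 46.9 (22.5 to 118), and Sema4f, a semaphorin, from 7 to 199 counts, a ratio of 27.6 (13.2 to 69.6). Ramp3, which encodes an accessory protein of calcitonin-family receptors, was listed at 0 counts untreated and at 239 after PTH. The chemokine genes Cxcl1 and Cxcl5 were listed at 0 untreated and at 67 and 64 after PTH, and Nap1l5, a nucleosome assembly family gene, at 0 and 51. The remaining rows of the 15, H2ac18, Evi2b and Gal3st4, were also listed at 0 untreated. They share 90.3%, 98.5% and 99.05% of their exonic length with another gene on the same strand, so their counts are uncertain. A further limit holds for every row listed at 0, and no fold is given for such rows. In all, 598 rows stood at 0 in 1 library and at 10 to 29 counts in the other, against 0.0353 expected from Poisson sampling. That expectation takes the higher count as the true mean, so it is a low estimate.

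The 10 rows ranked lowest were mostly of that kind. Usp50, a ubiquitin peptidase family gene, was listed at 138 counts untreated and 0 after PTH, Nipal4 at 131 and 0, Pvrig at 42 and 0, Aknad1 at 32 and 0, and Kcnj12 at 30 and 0. Zfp708 (85 and 0), AL731706.1 (90 and 0), Exosc6 (71 and 2), Snhg4 (1023 and 68) and Rmrp (234 and 18) share between 92.3% and 100% of their exonic length with another gene on the same strand, and their counts are uncertain. A second ranking, chosen after the data were seen, took protein-coding genes with at least 10 counts in each library and under 20% shared exonic length. Its lowest genes were Foxs1, a forkhead transcription factor, 7.49-fold lower (6.73 to 8.36), Jun, then Rgs3, which like Rgs2 limits G protein signalling, 5.74-fold lower (5.32 to 6.20). Tnfaip3, a ubiquitin-editing enzyme that restrains NF-kappaB, was 5.44-fold lower (4.99 to 5.94) and Cdk5r1, an activator of a neuronal cyclin-dependent kinase, 5.35-fold lower.

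In the list of cyclic AMP and CREB target genes, fixed like all lists before the data were examined, 15 of 17 measured members had more reads past the rule, 1 had fewer and 1 was neither. The median log2 ratio of 2.06 stood at percentile 100 among 10000 random lists of the same size matched on expression. Besides Rgs2, Nr4a2 and Crem, Nr4a3, a nuclear receptor related to Nr4a2, was 10.3-fold higher (10.0 to 10.6) and reached 50447 counts. Nr4a1, the third member of that family, was 2.21-fold higher (2.18 to 2.24) from 28309 counts untreated. Cited2, a transcriptional co-regulator, was the member with fewer reads, at a ratio of 0.328, and Fosb was neither, at 0.692. With the interval widened for the assumed coefficient of variation of 0.2, 11 members kept more reads by the rule, and Nr4a1 was among those that did not.

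Regulators of cyclic AMP and G protein signalling went in both directions. Of 18 measured members, 5 had more reads, 3 fewer and 10 neither, with a median log2 ratio of 0.06 at percentile 89.8. Sik1, a salt-inducible kinase, was 7.70-fold higher (7.45 to 7.96), and the phosphodiesterase genes Pde4b and Pde4d, whose products degrade cyclic AMP, were 4.67-fold (4.41 to 4.95) and 3.92-fold higher (3.70 to 4.16). The related Pde4a was at a ratio of 0.557. The receptor gene Pth1r itself was at a ratio of 0.803 (0.773 to 0.835) and not past the rule. Gprc5a, an orphan G protein-coupled receptor gene, was 8.30-fold higher (7.84 to 8.79), from 1355 to 11581 counts. It was named in advance because a study of PTH and this gene was recalled, so it is not an independent pick. Among MAP kinase feedback regulators, 5 of 15 had more reads, 4 fewer and 6 neither. Their median log2 ratio was -0.03, at percentile 34.7, while their mean was 0.26. The phosphatase gene Dusp1 was 5.62-fold higher (5.42 to 5.84), Spry2, an inhibitor of receptor tyrosine kinase signalling, 4.01-fold (3.78 to 4.26), Dusp10 2.48-fold and Dusp14 2.46-fold. Dusp4, Dusp6, Dusp8 and Dusp16 were the members with fewer reads, at ratios of 0.491, 0.512, 0.530 and 0.593. With the widened interval, Dusp1 and Spry2 were the members of this list still past the rule.

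Of 22 measured genes on the cytokine, chemokine and growth factor list, 13 had more reads after PTH and 9 were neither. Of the 13, 2 (Cxcl1 and Cxcl5) were listed at 0 untreated, so these 2 calls are uncertain. The 13 include Ptgs2, a prostaglandin-synthesising enzyme gene rather than a secreted factor, at 1.98-fold, and the median log2 ratio was 1.01, at percentile 100. Beyond Il6 and Tnfsf11, the members with more reads included Il11 at 14.2-fold, Areg, an EGF receptor ligand, at 10.6-fold, Vegfa, an angiogenic factor, at 5.17-fold, Ccl2 at 5.00-fold and Lif at 4.07-fold. These examples were picked after their values were seen. Tnfrsf11b, which encodes osteoprotegerin, the decoy receptor for RANKL, was at a ratio of 0.637 and not past the rule. Counts of Tnfsf11 were low in both libraries, at 12 untreated and 348 after PTH. With the widened interval 10 of the 13 kept more reads by the rule, Cxcl1 and Cxcl5 among them.

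**Figure D2:**
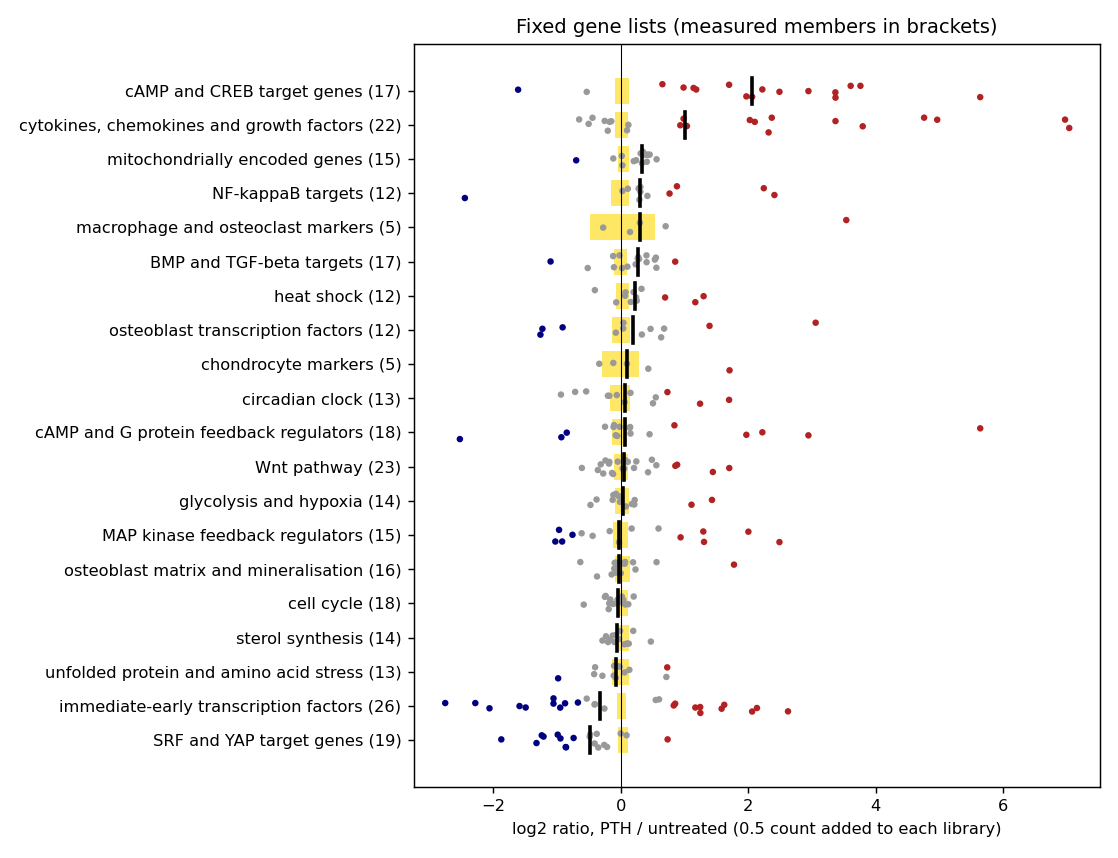
Log2 ratio of PTH to untreated counts (horizontal axis, 0.5 count added to each library) for the measured members of the 20 fixed lists with at least 5 such members; each point is 1 gene in 1 library per condition, red with more and blue with fewer reads past the rule of size. The black bar is the list's median and the yellow band holds 95% of the medians of random lists matched on expression; cyclic AMP targets (median 2.06) lie to the right of their band and SRF and YAP targets (median -0.48) to the left.

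The list of immediate-early transcription factors split evenly. Of 26 measured members, 10 had more reads, 10 fewer and 6 neither. The 10 with more reads include Zfp36 (ratio 1.81) and Ier3 (3.09), immediate-early genes that do not encode DNA-binding factors. The 10 with fewer include Ier2 (0.629), likewise not a classical DNA-binding factor. The list's median log2 ratio of -0.33 stood at percentile 0 of the random lists, while its mean was 0.01. Fos, the AP-1 partner of Jun, was 6.17-fold higher (5.88 to 6.48), and Cebpd, a bZIP transcription factor, 4.40-fold higher (4.24 to 4.57). Under 20% of the exonic length of Cebpd, and of Bhlhe41 in the clock list, overlaps exons of the opposite strand. Jun went from 12678 to 1940 counts, and Atf3, a stress-responsive bZIP factor, was 4.86-fold lower (4.18 to 5.67). Within the AP-1 genes, Fosl1 (2.38), Fosl2 (3.0) and Junb (1.78) had ratios above 1, and Jund (0.547) and Fosb (0.692) below 1. The zinc finger genes Egr1, Egr2, Egr3 and Egr4 all had fewer reads, at ratios of 0.482, 0.333, 0.356 and 0.240. With the widened interval 5 members kept more reads and 5 kept fewer.

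**Figure D3:**
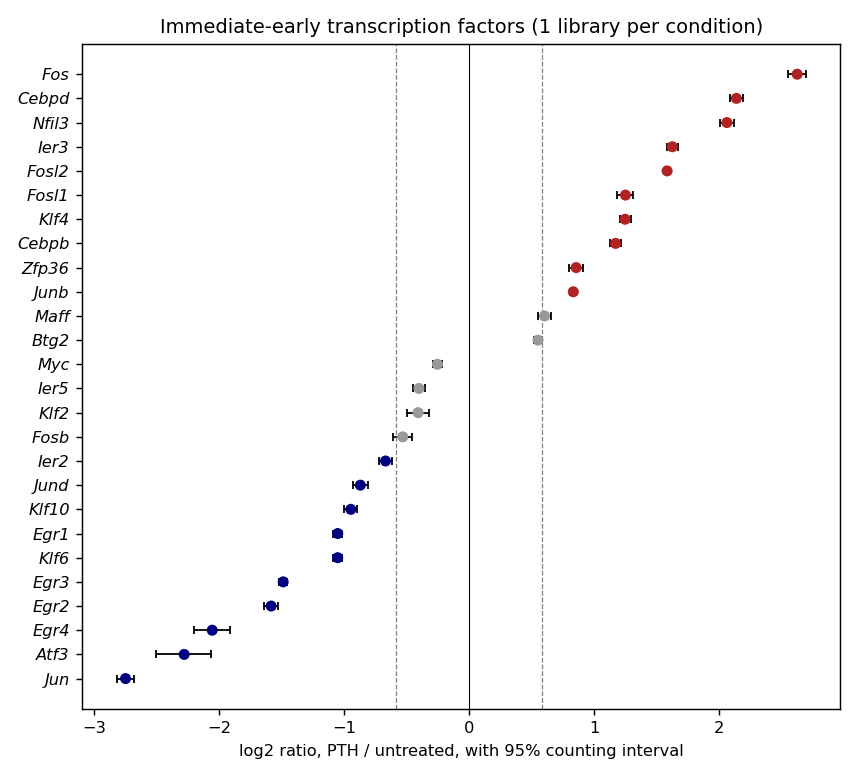
Log2 ratio of PTH to untreated counts (horizontal axis) for the 26 measured members of the immediate-early transcription factor list. Bars are 95% counting intervals, with 1 library per condition, and dashed lines mark 1.5-fold in each direction. Red points have more and blue points fewer reads past the rule of size, from Fos at 2.62 to Jun at -2.75.

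Targets of SRF and YAP, transcriptional regulators that respond to actin and cell shape, had a median log2 ratio of -0.48, at percentile 0 of the random lists. Of 19 measured members, 9 had fewer reads, 1 (Amotl2, at a ratio of 1.67) had more and 9 were neither. Besides Ccn2, the list held Ankrd1, a muscle and stress ankyrin protein gene, 2.49-fold lower (2.45 to 2.54), Srf itself, 2.36-fold lower (2.30 to 2.42), and Cnn1, which encodes an actin-binding calponin, 2.32-fold lower (1.91 to 2.81). Actb, which encodes cytoplasmic actin and has processed pseudogenes, was at a ratio of 0.550. With the widened interval, Ccn2 alone stayed past the rule in this list. Ccn2 overlaps other annotated exons on the opposite strand over 23.2% of its exonic length, and whether counting used strand is not given in the sources used here. In the BMP and TGF-beta list, Smad6, an inhibitor of BMP signalling, had more reads, at 1.81-fold (1.73 to 1.89), and was not past the rule with the widened interval. Of the 17 members 15 were neither, and the list's median was 0.27 at percentile 99.99.

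Among osteoblast transcription factors, Vdr, the vitamin D receptor gene, was 8.33-fold higher (8.12 to 8.55) and reached 56412 counts. Sp7, which encodes osterix, a factor required for osteoblast differentiation, was 2.39-fold lower (2.27 to 2.52), and the homeobox gene Msx2 2.34-fold lower (2.04 to 2.70). Runx2, a master regulator of the lineage, was at a ratio of 1.03 (1.01 to 1.06). In all, 2 of 12 members had more reads, 3 fewer and 7 neither, with a median log2 ratio of 0.19 at percentile 99.2. The other member with more reads, Twist2, at 2.64-fold (2.0 to 3.52), overlaps exons of the opposite strand over 46.5% of its length. Only Vdr stayed past the rule in this list with the widened interval. Of 16 measured osteoblast matrix and mineralisation genes, 15 were not past the rule, with ratios that included 0.643 (0.439 to 0.935) for Dmp1, 0.774 (0.730 to 0.820) for Ibsp and 1.48 (1.05 to 2.11) for Bglap. The member past it was Bglap2, an osteocalcin gene, at 3.48-fold (2.19 to 5.72) from 24 to 86 counts, which has near-identical copies, so the assignment of its reads is uncertain. This list's median was -0.03 at percentile 15.5, and its mean was 0.09.

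Of 23 measured Wnt pathway genes, 4 had more reads and none fewer past the rule, with a median log2 ratio of 0.06 at percentile 80.7. Wnt4, a Wnt ligand gene, was 3.26-fold higher (2.88 to 3.70), Fzd1, a Wnt receptor gene, 1.85-fold (1.81 to 1.89) and Lrp4, a co-receptor gene that binds sclerostin, 1.81-fold (1.76 to 1.87). Notum, which encodes a secreted Wnt inhibitor, was at 2.73-fold (2.25 to 3.34) but overlaps exons of the opposite strand over 38.1% of its length. Fzd1 and Lrp4 were not past the rule with the widened interval. Of 12 NF-kappaB targets, 4 had more reads, 1 (Tnfaip3) fewer and 7 neither, with a median of 0.31 at percentile 99.99. Bcl3, a nuclear IkappaB family gene, was 5.34-fold higher (4.35 to 6.61), Traf1, an adaptor of TNF receptors, 4.98-fold higher (2.30 to 12.3) from 8 to 41 counts, and Nfkbiz 1.84-fold higher (1.73 to 1.97), the last not past the rule with the widened interval.

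In the circadian clock list 3 of 13 members had more reads and 10 were neither, with a median log2 ratio of 0.06 at percentile 81.3. Per1, a period gene that also responds to cyclic AMP, was 3.25-fold higher (3.18 to 3.33), Bhlhe41 2.37-fold and Cry2 1.66-fold. Heat shock genes had 3 of 12 members with more reads, Hspb1 at 2.47-fold, Hsph1 at 2.25-fold and Bag3 at 1.62-fold, and 9 neither. Their median was 0.22 at percentile 99.94. In the unfolded protein and amino acid stress list, Ppp1r15a, which directs dephosphorylation of a translation initiation factor, was at 1.66-fold, and Chac1, a glutathione-degrading enzyme gene, was 1.97-fold lower (1.78 to 2.18). The other 11 of 13 members were neither and the median was -0.08 at percentile 10.3. In the glycolysis list Hk2, a hexokinase gene, was 2.70-fold higher (2.61 to 2.79), and Gapdh was at 2.16-fold with 2091 and 4653 counts. Gapdh has many processed pseudogenes, so its reads are uncertain. The other 12 of 14 members were neither and the median was 0.04 at percentile 61.9, and below 0 with total-count scaling. Bhlhe41, Cry2, Hspb1, Hsph1, Bag3, Ppp1r15a, Chac1 and Gapdh were not past the rule with the widened interval. None of 18 cell cycle genes and none of 14 sterol synthesis genes was past the rule, with medians of -0.03 at percentile 5.0 and -0.05 at percentile 3.25.

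Among markers of other cell types, 5 of 8 chondrocyte and 5 of 9 macrophage and osteoclast markers had enough counts to compare. Fewer did in the other lists, with 3 of 8 adipocyte, 2 of 8 muscle and 1 of 7 endothelial markers. Of the chondrocyte markers, Sox9, a cartilage transcription factor also present in immature skeletal cells, was 3.27-fold higher (3.14 to 3.40), and 4 of 5 were neither, including Col2a1 at a ratio of 1.35 (1.33 to 1.37). The list's median was 0.10 at percentile 79.8. Of the macrophage and osteoclast markers, Cd14, a lipopolysaccharide co-receptor gene, was 12.0-fold higher (6.96 to 22.4), from 14 to 173 counts. The other 4 of 5 were neither, including Ctsk at 1.11 (1.07 to 1.15), with a median of 0.30 at percentile 89.4. None of 3 adipocyte, 2 muscle and 1 endothelial marker with enough counts was past the rule, and Egfl7, the endothelial one, was at 1.25 (0.888 to 1.77). Of 15 mitochondrially encoded genes, 14 were neither, with mt-Co1, a cytochrome oxidase subunit gene, at a ratio of 1.24, and mt-Rnr1, a mitochondrial ribosomal RNA, was 1.62-fold lower (1.57 to 1.67). The list's median was 0.34 at percentile 99.99, mt-Rnr1 was not past the rule with the widened interval, and mitochondrially encoded genes took 2.22% of untreated and 2.73% of PTH counts. The nuclear ribosomal RNA row CT010467.1 took 1.09% of untreated and 0.405% of PTH counts, and 7 of 10 structured RNAs, a group formed after the data were seen, had fewer reads after PTH. The 7 include CT010467.1 and mt-Rnr1, and also Rn7s1 and Rn7s2, near-identical copies with uncertain reads.

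In the GRCm38 (mm10) assembly, with GENCODE release M21 coordinates, Rgs2 (ENSMUSG00000026360) lies on chromosome 1 from 143999338 to 144004161 on the minus strand. Il6 (ENSMUSG00000025746) lies on chromosome 5 from 30013114 to 30019981, plus strand, and Tnfsf11 (ENSMUSG00000022015) on chromosome 14 from 78277445 to 78308043, minus strand. Vdr (ENSMUSG00000022479) lies on chromosome 15 from 97854425 to 97910630, minus strand, Jun (ENSMUSG00000052684) on chromosome 4 from 95049034 to 95052222, minus strand, and Ccn2 (ENSMUSG00000019997) on chromosome 10 from 24595442 to 24598683, plus strand. The receptor gene Pth1r (ENSMUSG00000032492) lies on chromosome 9 from 110722085 to 110747145, minus strand. All of these are annotated as protein coding, and none of the 7 shares exonic length with another gene on the same strand.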

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

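The count alternatives were set before the data were examined, except those that leave out rows listed at 0, leave out rows sharing exons, or halve the counts, which were added after seeing the data. With total counts, median-of-ratios or upper-quartile scaling, 840 to 883 rows had more reads and 584 to 643 fewer past the rule, against 884 and 581. Thinning, summed symbols, rows at 0 left out and rows sharing exons left out gave 801 to 882 and 518 to 580. With no count filter there were 1386 and 983, with a minimum of 100 counts 543 and 307, with a 1.2-fold limit 1729 and 1459, and with a 2-fold limit 517 and 262. An assumed coefficient of variation of 0.1 gave 680 and 404, and of 0.2 gave 474 and 267; halved counts gave 661 and 376. The filters and limits change how many rows can pass, and the wider intervals let fewer pass by construction. Of the 20 list medians, that of osteoblast transcription factors (0.19) stood inside the range of random lists when these were not matched on expression, at percentile 97.1. The cause was not tested. The glycolysis median went from 0.04 to below 0 with total counts and was within the random range in both. All 81 named genes kept their direction and their side of the rule under the 3 other scalings and thinning, and 23 were no longer past the rule with the coefficient of variation of 0.2. No paired analysis was possible because each condition had 1 library, and for the same reason no library could be left out. Depth limits rows near the floor of 3 counts, 0.0447 CPM untreated and 0.0434 after PTH, and the excess of zeros leaves rows listed at 0 less certain than that.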

Other observations

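The groups in the opening paragraphs and the tests of explanations in this part were chosen after the results were seen, while the cyclic AMP and the SRF and YAP lists were fixed before. The groups have no test, and beside them 884 of all 16408 compared rows were past the rule of size with more reads. Of 8 measured neuropeptide and secretory granule genes, 6 were past the rule of size with more reads and none with fewer. Besides Vgf, Penk, the enkephalin precursor gene, went from 4 to 64 counts (ratio 15.5, 5.78 to 58.8), Scg2, a secretogranin gene, was 5.57-fold higher (3.93 to 8.08), Syt13 3.34-fold, Ptprn 3.11-fold and Bdnf, a neurotrophin gene, 2.83-fold, while Cpe was at a ratio of 1.07 and Scg5 at 0.785. Of 5 measured granzyme genes, which encode serine proteases best known from cytotoxic lymphocytes, 3 had more reads, with Gzmb at 11.7-fold (9.52 to 14.6) and Gzmc at 2.95-fold (2.60 to 3.34). Gzme, the other, was listed at 0 untreated and 28 after PTH. Of the macrophage and osteoclast list, the pan-leukocyte marker Ptprc, Itgam and Adgre1 were listed at 0 in both libraries. Lyz2 (201 counts untreated, 338 after PTH), Csf1r (122 and 155) and Cd68 (67 and 57) had counts, as did Cd14 and Ctsk, and Acp5 after PTH. The cell source of the granzyme reads was not tested.

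Of 11 measured developmental regulator genes, picked after values were seen, 7 had more reads and 1, Foxs1, had fewer. Beside Iroquois genes they hold Foxc1, Foxc2 and Foxs1 of the forkhead genes, Pax3 and Pax9 of the paired-type genes, Hlx and Mab21l1. The 7 of 11 is therefore not a share of whole gene families. Foxc2 was 6.69-fold higher (6.12 to 7.31), the homeobox gene Hlx 6.68-fold (6.33 to 7.05), Irx5 4.59-fold (4.39 to 4.79) and Pax3 3.35-fold (3.15 to 3.56), while Irx1 was at a ratio of 0.876 (0.825 to 0.931). Of 9 hyaluronan genes 3 had more reads past the rule, and the median log2 ratio was 0.29. The synthases Has1 and Has2 were 16.3-fold and 2.02-fold higher and Tnfaip6, which cross-links the hyaluronan matrix, 3.68-fold, while Has3 was at a ratio of 0.539 and not past the rule. Hdac5, a class IIa histone deacetylase controlled by salt-inducible kinases, was 3.76-fold higher (3.66 to 3.87), with its relatives Hdac4 at 0.843 and Hdac7 at 1.05. Il1rl1, the interleukin-33 receptor gene, was 9.94-fold higher (9.48 to 10.4) and reached 18998 counts. Ddit4, an inhibitor of mTOR signalling, was 8.51-fold higher (7.94 to 9.13).

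The cyclic AMP target list had a higher and the SRF and YAP list a lower median than random lists, and these medians were 2.55 apart on the log2 scale. GC content or gene length bias is argued against, since the medians were 2.57 apart after both trends were removed. Handling that stimulated the PTH well more is left open, since 10 members of the immediate-early list had fewer reads there and 10 had more. Stronger serum or mechanical stimulation of the untreated well could also lower the SRF and YAP list, whose median was -0.48, and cannot be told apart from an effect of PTH with 1 library per condition. A direct effect of the hormone on these targets is a hypothesis that was not tested here.

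Of 10 structured RNAs, which usually lack a poly(A) tail, 7 had fewer reads, including Rn7sk at a ratio of 0.319 and the signal recognition particle RNAs Rn7s1 (0.115) and Rn7s2 (0.112), near-identical copies whose reads cannot be assigned with certainty. The 7 also include the nuclear ribosomal RNA row, which went from 1.09% to 0.405% of counts, mt-Rnr1 and Rmrp. Replication-dependent histone genes had a median log2 ratio of -0.63, with 15 of 54 fewer and 1 more. Many of them have near-identical copies, so the assignment of their reads is uncertain. The 1 with more, H2ac18, was listed at 0 untreated and shares 90.3% of its exonic length with another gene on the same strand. Fewer S phase cells in the PTH well was not seen in 8 S phase genes, whose median log2 ratio was -0.0143. Their ratios ran from 0.670 for Ccne1 to 1.15 for Pcna. Whether these transcripts would follow a change in DNA synthesis within 1 h was not tested, so this explanation is left open. Less carry-over of RNA without a poly(A) tail could account for both groups but is left open, because 71 snoRNA rows had a median of 0.45 and 20 mitochondrial tRNA rows 0.40, both above the range of random lists. How the RNA was selected is not given in the sources used here, and no biological explanation was tested.

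Rows listed at 0 in 1 library and at 10 to 29 counts in the other numbered 598. Poisson sampling gave an expected 0.0353 with the higher count taken as the true mean, which is a low estimate. The size of the gap still argues against sampling alone. Shared exons on the same strand are argued against as the main source, since 8.36% of these rows have any. Overlap on the opposite strand and near-identical copies elsewhere were not counted here, so reads assigned to other genes are left open. In the PTH library rows at 0 outnumbered rows at 1 by 20.6 to 1 (268 against 13). In the untreated library the ratio was 14.35 to 1 (330 against 23). Any source of extra zeros would give such ratios, so low rows having been set to 0 during the authors' counting is left open. Rows at 2, 3 and 4 numbered 29, 58 and 102 in the PTH library and 48, 68 and 126 in the untreated library. Zeros were not limited to low rows, since 9 rows stood at 0 in 1 library and at 100 or more in the other. Of these 9, 4 had all exons shared on the same strand. No biological explanation was tested. Of the rows past the rule, 83 were at 0 untreated and 63 at 0 after PTH, among them Ramp3, Cxcl1 and Usp50.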
